A study of Mus musculus with 12 samples.

How the data were processed

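Kidney RNA from C57BL/6 mice was measured by QuantSeq, a Lexogen method that sequences the 3' end of polyadenylated transcripts, so that each transcript gives reads near its end and gene length does not enter the values. The 12 libraries fall into 3 groups of 4 by their labels: Control, chronic kidney disease (CKD), and CKD with time restricted feeding (CKD TRF). How the disease was induced, the feeding hours and the hour of collection are not given in the sources used here. Nothing in the labels says that the 4 libraries of a group come from separate animals, so the p-values measure only the spread between these samples.

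Bowtie2, bedtools and the mm10 genome build are named per the submitters' processing notes, without versions. The values the authors deposited are on a log2 scale, 1 file per library with gene symbols. Low values in each file are log2(CPM + 1) of whole read numbers, where CPM is the count per M reads of an effective library size that differs from the plain total by a factor the authors applied. The factor was recovered from the values and lies between 0.847 and 1.062. It ran from 0.847 to 0.929 in Control, from 1.022 to 1.062 in CKD and from 0.975 to 1.012 in CKD TRF. The factor thus did not overlap between groups, and its effect cannot be separated from that of the group. With this factor, 100% of the values up to 100 reads came out whole in every library, within a tolerance of 6e-04 on the log2 scale. Recovered totals ran from 10.99 to 12.81 M reads in Control, from 14.51 to 16.86 M reads in CKD and from 14.15 to 17.21 M reads in CKD TRF. No molecular identifiers were used in these values, so floors cover counting error only. A floor of 3 reads corresponds to 0.255 to 0.306 CPM in the Control libraries and to 0.168 to 0.215 CPM in the other libraries. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes cannot be separated, and near-identical copies share reads.

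The files list 23282 entries with 23238 distinct symbols, of which 35 are repeated. Of the entries, 95.2% matched a gene of the GENCODE annotation of GRCm38, the assembly also called mm10, from which identifiers and 1-based coordinates were taken. A gene was kept when at least 4 of the 12 libraries had a value of 2 or more, that is 3 CPM, which left 12132 genes. Replicate pairs within groups differed by more than counting noise, with a chi-square per degree of freedom from 3.88 to 8.81 over 18 pairs, so no pair looked like 1 library sequenced again.

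Group means were fitted with limma 3.58.1 in R 4.3.3 over all 12 libraries in 1 model, with a mean-variance trend and robust moderation and without a replicate block. P-values were adjusted by the Benjamini-Hochberg method within each of the 3 comparisons, and genes at an adjusted p under 0.05 were called. The plan named a count model for files of counts and this limma fit for log values, and the log values took the limma fit. A fold change is a difference of log2(CPM + 1) values, which understates the change of genes with few reads. In simulated libraries with known changes, 5.8% of the calls between CKD and Control, 2.5% between CKD TRF and CKD and 5.1% between CKD TRF and Control were false. The simulated noise of each gene was independent, without shifts of a whole library, so the rates in the real libraries may differ.

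Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction without setting them against other genes, were run beside it. Of 46 lists, 43 with at least 5 measured members were tested. The neutrophil list (4 of 18 members measured), the adrenal cortex list (3 of 12) and the skeletal muscle list (2 of 14) were not tested. An exact two-sided permutation test of each list's mean per library was added, for which 4 against 4 libraries allow 70 labelings and no p under 0.0286.

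The groups, tests, gene lists, named-gene rule and the first set of alternative settings below were fixed before the data were examined. By that rule, the named genes of a comparison are the 10 with the largest positive and the 10 with the largest negative fold change among called genes whose groups do not overlap, leaving out predicted or unnamed models. Where no gene is called, the 10 with the smallest unadjusted p are given as values only. Up to 4 members of each described list, those with the smallest p, and all members of the clock lists are also named. Some genes that the rule picks are left out of the text and figures. Which lists are described, and the use of 2 members each, were decided after the values were seen, the latter partly to limit how many groups were searched for outlying samples.

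The alternative settings fixed beforehand were median centring, quantile normalization, limma without trend and robust moderation, array weights, no filter and a stricter filter of 15 CPM, a pseudocount of 2, the 2 groups alone, the replicate number as a block, 2-fold thresholds, the other list tests and leaving out each library. Alternatives added after seeing the data were limma-voom on the recovered reads, scaling to plain totals, reads thinned to the shallowest library, the adipocyte list as a covariate, leaving out libraries with an Adipoq value over 3, leaving out CKD replicates 2 and 4, and the permutation of list means. Because CKD libraries enter both the disease effect and the feeding effect, the share of the disease effect that remains was estimated by cross-fitting. Genes were chosen in 2 of the CKD and 2 of the Control libraries, and the slope was taken with the other libraries, over all 36 combinations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.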

Results

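Transcript levels were compared in kidneys of Control mice, mice with chronic kidney disease and diseased mice kept on time restricted feeding, with 4 libraries in each group. Library totals were 10.99, 12.81, 12.66 and 12.05 M reads in Control replicates 1 to 4. They were 14.51, 16.8, 16.86 and 14.64 M reads in CKD and 14.15, 15.34, 17.21 and 15.03 M reads in CKD TRF, so that every Control library was shallower than every other library. The ribosomal RNA precursor Rn45s took 7.43% ± 2.71 (SD, n = 4) of the reads in Control, 10.46% ± 0.94 in CKD and 11.92% ± 0.97 in CKD TRF. Kap, an abundant androgen-regulated transcript of the mouse proximal tubule, took 4.44% ± 0.6 in Control, 2.73% ± 0.26 in CKD and 2.79% ± 0.32 in CKD TRF. The first principal component held 60.8% of the variance, with Control libraries between -55.4 and -39.8 and all other libraries between 15.9 and 35.2.

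The comparison of CKD with Control asks how the diseased kidney differs. Genes of the extracellular matrix, macrophages, fibroblasts and tubular injury rose in CKD, and genes of the proximal tubule fell. Gabrp, a subunit of the GABA type A receptor, reached 33.7 ± 2.73 CPM (SD, n = 4) in CKD against 0.0739 ± 0.0969 CPM in Control, where it lay under the floor of 3 reads. Smoc2, a secreted matrix-associated protein, rose from 12.6 ± 2.73 to 212.1 ± 24.1 CPM. Cckar, the cholecystokinin A receptor, fell from 461.9 ± 43.2 to 119.7 ± 18.4 CPM. In limma 2886 genes were higher and 2992 lower in CKD at an adjusted p under 0.05, 48.5% of the 12132 tested, of which 983 and 295 changed at least 2-fold. The groups did not overlap for 42% of genes, where chance gives 2.9%. Scaling to plain totals, chosen after seeing the data, moved the median of all genes by 0.21 on the log2 scale and gave 4474 higher and 1511 lower genes. Leaving out the libraries with an Adipoq value over 3 left 1861 higher and 1946 lower genes, with 2 CKD libraries in the fit.

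Among the genes with the largest changes, Gabrp (chromosome 11, 33550781 to 33578959, minus strand) had a log2 fold change of 5.01 ± 0.17 (SE), adjusted p = 3.05e-15. Gpnmb, a transmembrane glycoprotein expressed by macrophages (chromosome 6, 49036546 to 49070929, plus strand), followed at 4.85 ± 0.20, adjusted p = 5.94e-14. The chemokine Ccl8 rose by 4.54, the lysozyme Lyz1 by 4.20, Igfbp2 by 4.12, Smoc2 (chromosome 17, 14279506 to 14404790, plus strand) by 3.99, and Lcn2, a marker of tubular damage, by 3.82. The matrix glycoprotein tenascin C, encoded by Tnc, rose by 3.70. Cfd, which encodes the complement protease adipsin made by fat cells, had a log2 fold change of 4.54 ± 1.65 at an adjusted p of 0.0455. This call was lost in 16 of 27 alternative settings, and Cfd ran from 2.09 to 258 CPM within CKD. Reads of Lyz1 can be shared with its close copy Lyz2, which leaves the split between them uncertain.

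The largest decreases included hemoglobin alpha (Hba-a2, -2.70 ± 0.55, SE, adjusted p = 0.00284), Akr1c18 (-2.01) and the chemokine Ccl28 (-2.01). Cckar (chromosome 5, 53697776 to 53707705, minus strand) fell by 1.95 ± 0.12 on the log2 scale, adjusted p = 4.65e-11. The beta globins Hbb-bt and Hbb-b2 changed by -1.94 and -1.91, and Sdhd, a subunit of succinate dehydrogenase, by -1.94. Over the alternative settings the adjusted p of Hba-a2 ran from 0.000364 to 0.0754 and that of Sdhd from 0.00242 to 0.111, with log2 fold changes from -2.97 to -2.23 and from -2.28 to -1.49. Both calls were lost when the libraries with an Adipoq value over 3 were left out, which leaves fewer libraries in the fit. Cyp4a12a, a fatty acid hydroxylase, changed by -1.91, and Cyp4b1-ps2, a pseudogene of Cyp4b1, by -1.90. Values of the globins, of Cyp4a12a and of Cyp4b1-ps2 are uncertain because near-identical copies exist. Hbb-b2 had no match in the annotation used.

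**Figure D1:**
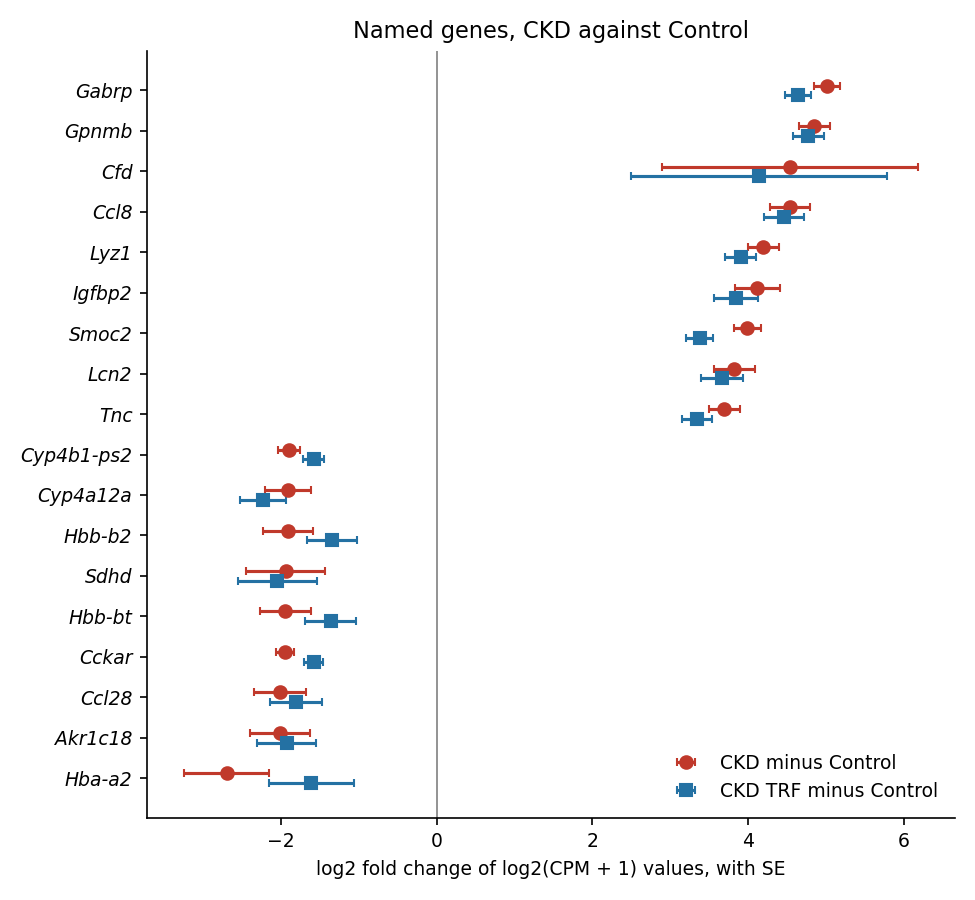
Horizontal axis: log2 fold change of log2(CPM + 1) values with SE; vertical axis: genes named in the comparison of CKD with Control, circles for CKD minus Control and squares for CKD TRF minus Control (4 libraries per group). Gabrp lies at 5.01 in CKD and 4.64 in CKD TRF, and the wide bars belong to Cfd, a transcript of fat cells.

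Structural and immune gene groups were higher in CKD. Of the 38 measured members of the extracellular matrix list, 37 rose and 1 did not pass, with the same 37 when adjusted over the list alone; Col3a1 rose by 3.04 ± 0.12 (SE) and Col1a1 by 3.04 ± 0.13. All 27 macrophage markers rose, also when adjusted over the list alone, with Lyz1 at 4.20 and the protease cathepsin S (Ctss) at 2.29. For tubular injury 26 of 32 members rose, 2 fell and 4 did not pass, the same counts adjusted over the list alone, with Cd44 at 3.07 and Lgals3 at 1.62. Among 26 chemokine, cytokine and adhesion genes 22 rose and 4 did not pass (23 adjusted over the list alone), including Ccl8 and Vcam1 (2.40). Of 18 complement genes 16 rose and 2 fell, also adjusted over the list alone, with the C1 inhibitor gene Serping1 at 2.27 and C1qb at 1.86. Of 20 fibroblast, pericyte and smooth muscle markers 15 rose, 1 fell and 4 did not pass (17 and 2 adjusted over the list alone), with Dcn at 2.24 and Pdgfra at 1.95. Of 30 T and NK cell markers only 7 were measured. Of these 6 rose and 1 did not pass (6 adjusted over the list alone), with Il7r at 2.81 and Thy1 at 1.68. Their mean was 1.48 in Control and 2.89 in CKD, while the filter asks for a value of 2 in 4 libraries. Such members can pass the filter through diseased libraries alone, which favors genes that rise. Camera called these 7 lists, with adjusted p from 1.22e-24 for the matrix list to 0.000221 for T and NK cells. With an estimated correlation their adjusted p ranged from 0.00789 to 0.0467. Some lists share members, so their calls are not independent. Dcn is in the matrix and fibroblast lists, and C1qb in the complement and macrophage lists. Vcam1 is in the injury and chemokine lists, and Lgals3 in the injury and macrophage lists. In the same comparison the fat gene Adipoq stood at 38.1 and 58.7 CPM in CKD replicates 2 and 4, against 1.88 and 1.04 CPM in replicates 1 and 3 and 0.138 CPM on average in Control.

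Antigen presentation, interferon and some nephron marker groups were also called higher. All 7 measured MHC class II genes rose, also adjusted over the list alone, with Cd74 at 2.07 ± 0.15 (SE) and Ctss at 2.29. This list had an adjusted p of 1.79e-05, and adjusted p = 0.212 with an estimated correlation. Of 37 interferon response genes 26 rose, 1 fell and 10 did not pass, the same adjusted over the list alone, with Ifi27l2a at 1.83 and Rtp4 at 1.65 (adjusted p = 2.2e-06 for the list, and adjusted p = 0.21 with an estimated correlation). Of 20 podocyte markers 12 rose and 8 did not pass (12 higher and 1 lower adjusted over the list alone), with the transcription factor Tcf21 at 1.55. The podocyte list had an adjusted p of 0.00253, and adjusted p = 0.137 with an estimated correlation. Of 16 principal cell markers 9 rose, 1 fell and 6 did not pass (10 and 1 adjusted over the list alone), with Gata3 at 42.2 CPM in CKD and 16.3 CPM in Control and the kinase gene Sgk1 at a log2 fold change of 1.49. The principal cell list had an adjusted p of 0.0126, and adjusted p = 0.368 with an estimated correlation, and its call was also lost with plain totals and with the adipocyte list as a covariate. The mean of the principal cell list was at least 5.45 in CKD replicates 2 and 4, where Adipoq was high, and at most 5.26 in replicates 1 and 3.

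Proximal tubule, organic anion transport and most energy metabolism lists were called lower by camera. Of 57 proximal tubule markers 48 fell and 9 did not pass (49 adjusted over the list alone), with the transcription factor Hnf4a at -1.10 ± 0.10 (SE); the list had an adjusted p of 8.75e-15, and adjusted p = 0.0467 with an estimated correlation. Of 71 respiratory chain genes 66 fell and 5 did not pass (67 adjusted over the list alone), with Ndufb3 at -1.38 and Ndufa5 at -1.06. The respiratory chain list had an adjusted p of 1.06e-16, and adjusted p = 0.232 with an estimated correlation. Of 30 organic anion transport and cytochrome P450 genes 23 fell, 2 rose and 5 did not pass (23 and 3 adjusted over the list alone), with Ugt3a1 at -1.28 and Cyp2e1 at -0.86 (adjusted p = 7.51e-07 for the list, and adjusted p = 0.114 with an estimated correlation). Gluconeogenesis and amino acid catabolism had 19 of 32 members lower and 13 not passed (19 adjusted over the list alone), with Dao at -1.18 and Mccc1 at -0.90 (adjusted p = 2.13e-06, and adjusted p = 0.0929 with an estimated correlation). The tricarboxylic acid cycle had 11 of 20 lower and 9 not passed (11 lower and 1 higher adjusted over the list alone), with Dlst at -0.76 and Sdhb at -0.82. For that list the adjusted p was 0.00298, and adjusted p = 0.294 with an estimated correlation; quantile normalization also ended the call. Of 48 fatty acid oxidation genes 20 fell, 6 rose and 22 did not pass, the same adjusted over the list alone, with Fabp3 at -0.98 and Acadm at -0.79. The mean of the fatty acid oxidation list was -0.14 as deposited, 0.08 with plain totals and 0.006 with quantile normalization. Its adjusted p was 0.0173, and adjusted p = 0.457 with an estimated correlation, and the exact permutation test did not call it (adjusted p = 0.266). Glycolysis was not among the lower lists: 7 of its 16 genes rose, 4 fell and 5 did not pass, the same adjusted over the list alone, with a mean of 0.32. Camera did not call it (adjusted p = 0.254), while it was called higher by fry, the permutation and quantile normalization (adjusted p from 0.012 to 0.567 over 30 settings).

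Among 11 erythroid genes 9 fell, 1 rose and 1 did not pass, the same adjusted over the list alone, with the heme synthesis gene Alas2 at -1.65 ± 0.31 (SE) and Hbb-bt at -1.94. Hbb-bs stood between 1582 and 3765 CPM in Control and between 508.5 and 995 CPM in CKD. The erythroid list had an adjusted p of 0.00104, and adjusted p = 0.289 with an estimated correlation. Of 76 cytosolic ribosomal protein genes 37 fell, 2 rose and 37 did not pass, the same adjusted over the list alone, with Rpl4 at -0.97 and Rpl11 at -0.96, both of which have pseudogenes that can share reads. The ribosomal list had an adjusted p of 1.4e-05, and adjusted p = 0.567 with an estimated correlation, and was not called by the permutation test or with quantile normalization. Of 12 measured adipocyte transcripts Plin4 and Cfd rose and 10 did not pass (1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.0562). The adipocyte list was called in 9 of 30 settings, the replicate block, array weights and the 2 groups alone among them, with adjusted p from 0.00949 to 0.992 over all 30. Camera called 24 lists, 15 higher and 9 lower, of which 8 held with an estimated correlation: the 7 structural and immune lists above 0 from the matrix to T and NK cells, and the proximal tubule. For 3 lists without a call (NRF2 and glutathione, heat shock, hypoxia) the list mean lay above 0 while the median and the test pointed down, and centring each library on its median brought these means below 0.

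**Figure D2:**
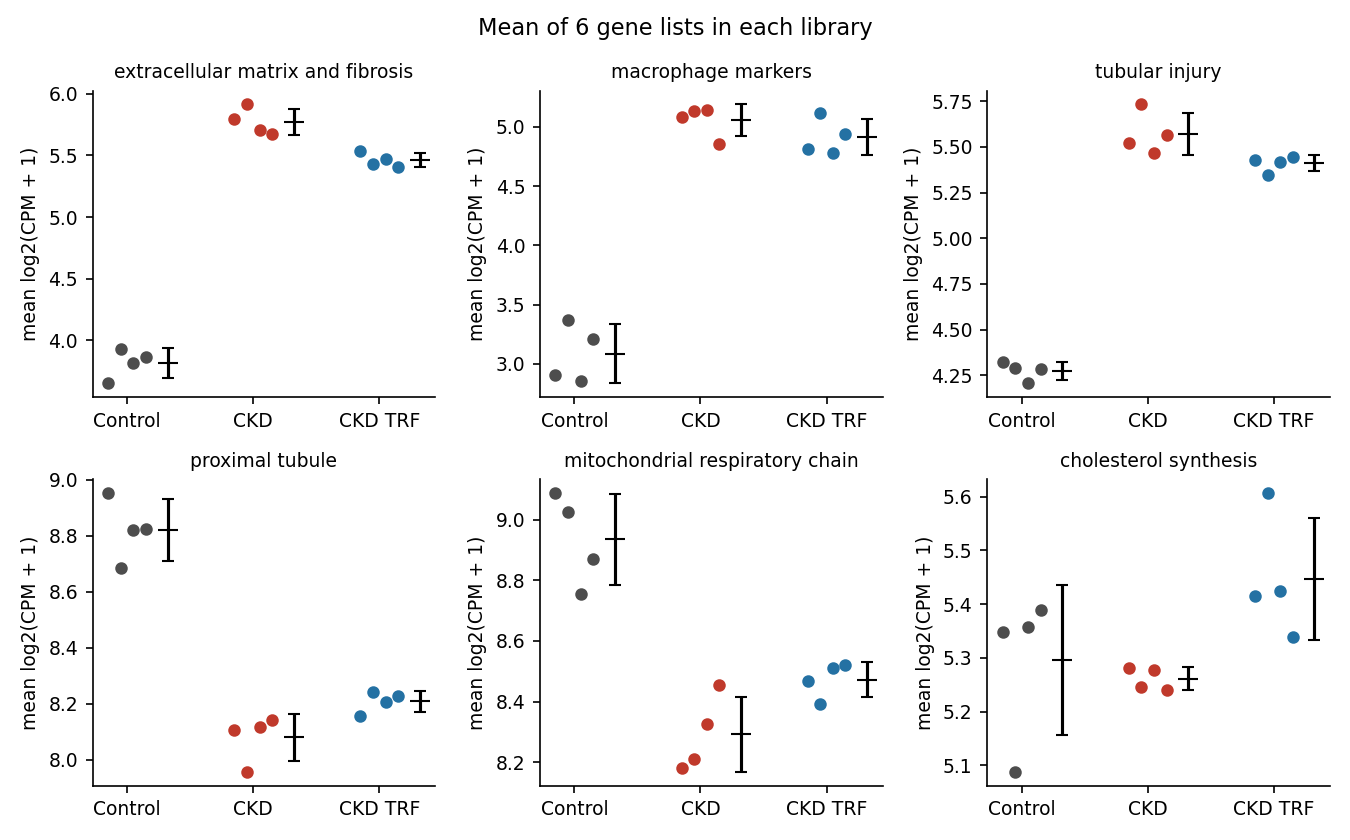
Each panel plots the mean log2(CPM + 1) of a gene list (vertical axis) in every library, by group (horizontal axis), with bars for the mean and SD of 4 libraries; the vertical axes differ and do not start at 0. The matrix list averaged 3.82 in Control, 5.77 in CKD and 5.46 in CKD TRF, and the proximal tubule list 8.82, 8.08 and 8.21.

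**Figure D3:**
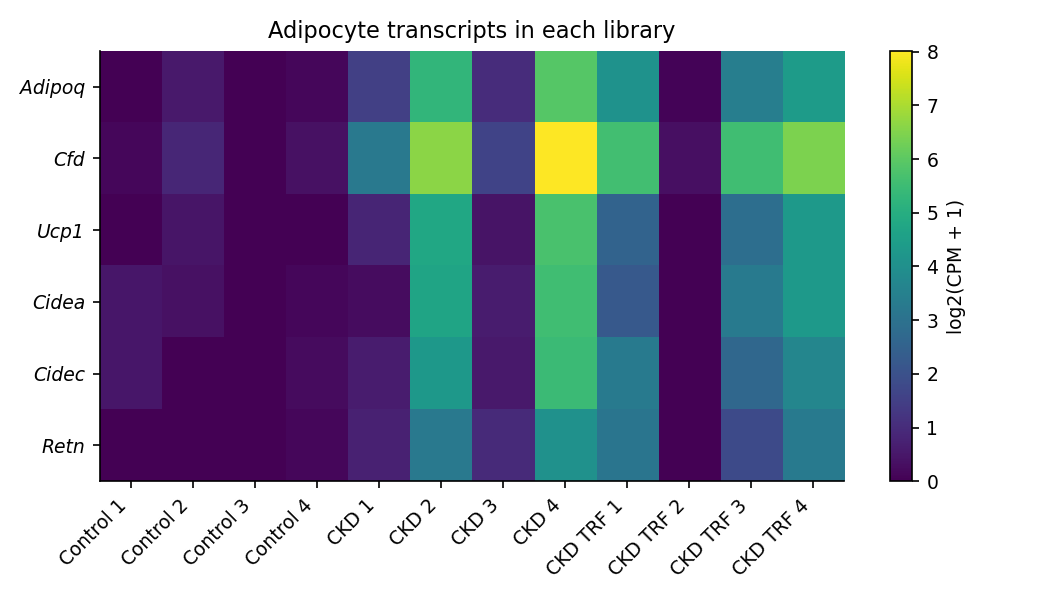
Color gives log2(CPM + 1) of 6 adipocyte transcripts (vertical axis) in each of the 12 libraries (horizontal axis). Adipoq was 5.29 and 5.90 in CKD replicates 2 and 4, 4.10, 3.44 and 4.40 in CKD TRF replicates 1, 3 and 4, and at most 1.53 in the other libraries.

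The comparison of CKD TRF with CKD asks what time restricted feeding changed in the diseased kidney. No gene passed the test, and the values below are given without a call. Matrix and injury genes had lower averages in CKD TRF than in CKD, and proximal tubule, respiratory chain and cholesterol synthesis genes had higher averages. Gpx3, the secreted glutathione peroxidase (chromosome 11, 54902453 to 54910377, plus strand), stood at 20580 ± 845 CPM (SD, n = 4) in CKD TRF and 14250 ± 2870 in CKD; over 27 settings its log2 fold change ran from 0, with quantile normalization, to 0.73, and its adjusted p from 0.0507 to 1. Limma called 0 genes higher and 0 lower, with a smallest adjusted p of 0.717; 783 genes had an unadjusted p under 0.05, where chance gives 607. Limma-voom on the recovered reads also called 0 (943 at the unadjusted threshold), and so did limma without trend (782). The groups did not overlap for 4.7% of genes, where chance gives 2.9%. In the self-test for this comparison limma recovered 45.5% of 1.5-fold, 83.3% of 2-fold and 95.5% of 4-fold changes. Its noise was drawn independently for each gene, without shifts of a whole library, so recovery in the real libraries may be lower.

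The 10 genes with the smallest unadjusted p all had an adjusted p of 0.717. Ccdc151 (chromosome 9, 21989871 to 22002634, minus strand), a gene of motile cilia, had a log2 fold change of 1.00 ± 0.21 (SE). Gpx3 and the nutrient-sensing GTPase gene Rraga each had 0.55, the sulfate transporter gene Slc26a1 0.45, Elovl2 0.56, Miox 0.52 and the transferrin receptor gene Tfrc 0.42. Sox11 had -1.06 ± 0.25, Wscd2 -1.10 and the neurotrophin receptor gene Ntrk2 -1.04.

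Of the 43 lists, camera with the preset correlation called 8 higher and 10 lower in CKD TRF than in CKD. None was called with an estimated correlation (lowest adjusted p = 0.15), by fry or by the exact permutation test (lowest adjusted p = 0.176). The permutation test cannot give a p under 0.0286, which 7 lists reached. After adjustment over 43 lists it could call a list only if many more reached that p, so its lack of calls decides little. Without CKD replicate 2 the preset test called 10 lists. In the extracellular matrix list 37 of 38 fold changes lay below 0, with a mean of -0.31, and 10 were lower when adjusted over the list alone, including Col1a2 (-0.37 ± 0.10, SE). The matrix list had adjusted p = 8.86e-15, and adjusted p = 0.15 with an estimated correlation. Among 32 tubular injury genes 23 lay below 0 and 0 passed adjusted over the list alone, with Cdkn1a at -0.45 and Cd44 at -0.56, and adjusted p = 0.15 with an estimated correlation. Fibroblast, pericyte and smooth muscle markers had 16 of 20 values below 0 and 0 passed adjusted over the list alone, with Acta2 at -0.50 and Pdgfra at -0.30, and adjusted p = 0.15 with an estimated correlation. Proximal tubule markers had 45 of 57 values above 0, a mean of 0.13 and 4 higher adjusted over the list alone, including Miox and the glucose transporter gene Slc5a2 (0.47 ± 0.14). Respiratory chain genes had 69 of 71 values above 0 and a mean of 0.18, with 0 passed adjusted over the list alone, Ndufb5 at 0.35 and Atp5g1 at 0.34. Cholesterol synthesis had 20 of 25 values above 0 and 0 passed adjusted over the list alone, with Msmo1 at 0.42. For the proximal tubule, respiratory chain and cholesterol lists the adjusted p was 8.77e-05, 8.86e-15 and 7.82e-05, and adjusted p = 0.417 with an estimated correlation for each. The other lists called higher by the preset test were erythroid, gluconeogenesis, NRF2 and glutathione, unfolded protein response and ribosomal proteins, with adjusted p from 3.4e-09 to 0.0441, and the mean of the unfolded protein list was 0.08 as deposited and -0.006 with plain totals. Those called lower were chemokines, macrophages, intercalated cells, clock output, fatty acid oxidation, glucocorticoid response and p53 targets, with adjusted p from 0.00213 to 0.0464. Of 30 settings, from 6 (glucocorticoid response) to 19 (intercalated cells) lost these calls. The macrophage call was lost in 8, and the mean of that list did not keep its sign over the settings. The adipocyte list mean was 3.96 ± 1.15 in CKD TRF and 4.24 ± 1.64 in CKD (SD, n = 4). For 6 lists without a call, among them interferon response, endothelial and cell cycle, the mean, the median and the test differed in sign.

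The comparison of CKD TRF with Control asks how far diseased kidneys under time restricted feeding stand from healthy ones. Matrix, macrophage and tubular injury genes rose here too, and genes of the proximal tubule and the respiratory chain fell, lists with adjusted p = 0.0618 and adjusted p = 0.316 with an estimated correlation. Gpnmb reached 35.5 ± 13.1 CPM (SD, n = 4) against 0.292 ± 0.216 in Control, and Cyp4a12a fell from 567.1 ± 59.7 to 120.1 ± 11.6 CPM. Limma called 2446 genes higher and 2484 lower, 40.6% of those tested, of which 797 and 166 changed at least 2-fold, and the groups did not overlap for 34.1% of genes. With plain totals the median of all genes moved by 0.13 on the log2 scale, 70.4% of the called genes were higher and 1402 were lower. Leaving out the libraries with an Adipoq value over 3 left 769 higher and 704 lower genes, with 1 CKD TRF library, which is then assumed to vary like the other groups.

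Gpnmb (4.77 ± 0.20, SE), Gabrp (4.64 ± 0.17), Ccl8 (4.46) and Lyz1 (3.91) led the increases, followed by the prostate stem cell antigen gene Psca (3.89), Igfbp2 (3.84) and Lcn2 (3.67). Dio2, the type 2 deiodinase that activates thyroid hormone, rose by 3.38, Smoc2 by 3.38 and Tnc by 3.35. Cyp4a12a changed by -2.23 ± 0.30, Sdhd by -2.05, Akr1c18 by -1.92, Acyp2 by -1.84, Mrps28 by -1.82 and Ccl28 by -1.81. Hacd2 changed by -1.67, Smcp by -1.64, Hba-a2 by -1.61 and Cyp4b1-ps2 by -1.58. The call of Hba-a2 (adjusted p = 0.0424) was lost in 13 of 27 settings, over which its adjusted p ran from 0.0146 to 0.441.

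In CKD TRF against Control 36 of 38 matrix genes rose and 2 did not pass (36 adjusted over the list alone), with Col3a1 at 2.63 ± 0.12 (SE) and Col1a1 at 2.64. All 27 macrophage markers rose, also adjusted over the list alone, with Lyz1 at 3.91 and Ctss at 2.12. Of 32 tubular injury genes 25 rose, 1 fell and 6 did not pass, the same adjusted over the list alone, with Lgals3 at 1.60. Of 57 proximal tubule genes 42 fell and 15 did not pass (42 lower and 1 higher adjusted over the list alone), with Aadat at -1.58 and Slc7a13 at -1.33. That list had an adjusted p of 1.02e-12, and adjusted p = 0.0618 with an estimated correlation. Of 71 respiratory chain genes 51 fell and 20 did not pass (55 adjusted over the list alone), with Ndufb3 at -1.29 and Uqcrc2 at -0.76, and adjusted p = 0.316 with an estimated correlation. Fatty acid oxidation had 22 of 48 genes lower, 3 higher and 23 not passed (23 and 3 adjusted over the list alone), with Slc27a2 at -0.79 and Decr2 at -0.79, and adjusted p = 0.33 with an estimated correlation; its call was lost with quantile normalization. Camera called 25 lists, 16 higher and 9 lower, of which 7 held with an estimated correlation: matrix, tubular injury, chemokines, complement, macrophages, T and NK cells, and fibroblasts. For 4 lists without a call, among them intercalated cells and hypoxia, the mean, the median and the test differed in sign.

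Calls of the 2 comparisons with Control were set side by side. Of the genes called in CKD, 2250 were also higher in CKD TRF and 2254 also lower, against 582 and 613 for independent lists, and 0 were called in opposite directions. With the Control libraries split so that the comparisons shared none, an average of 1458 higher and 1391 lower calls were shared, against 376 and 368 for independent lists. There were 1374 genes called only in CKD and 426 only in CKD TRF, and 0 of them passed the test of the difference between CKD TRF and CKD in limma. Across genes, which are not independent replicates, the fold changes of CKD and CKD TRF against Control correlated with r = 0.958, where unchanged groups sharing these controls gave 0.502. The covariance was 0.3668 against a simulated 0.0177, and r was 0.856 with split controls. In the simulated groups the noise of each gene was drawn independently, without shifts of a whole library.

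The share of the CKD effect that remained in CKD TRF was 0.862 by cross-fitting over 36 combinations (SD 0.031, range 0.806 to 0.911). Simulated libraries without a feeding effect gave an average of 0.967 over 5 simulations. The simulations here drew the noise of each gene independently, so no simulated library was shifted as a whole. The gap between 0.862 and 0.967 therefore does not separate a feeding effect from variation between whole libraries. The combinations reuse the same libraries, so their SD is not a standard error. Disease effect and feeding effect correlated across genes with r = -0.506, and simulated unchanged groups gave -0.493 because CKD libraries enter both with opposite sign. The covariance was -0.0645 against a simulated -0.0173, and -0.05 with the CKD libraries split between the effects.

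Each library was also placed between the Control mean (0) and the mean of the 8 diseased libraries (1) over 6130 genes, a measure chosen after the principal components had been seen. CKD libraries lay at 1.045, 1.168, 1.004 and 1.019, with a mean of 1.059 ± 0.074 (SD, n = 4). CKD TRF libraries lay at 0.96, 0.917, 0.939 and 0.947, with a mean of 0.941 ± 0.018. The difference of -0.118 had an exact permutation p of 0.0286 (two-sided, 70 labelings), the smallest these group sizes can give, which restates the separation on the first principal component. It was -0.082 with CKD replicate 2 left out of the average, while that library still entered the choice of genes, weights and scale.

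**Figure D4:**
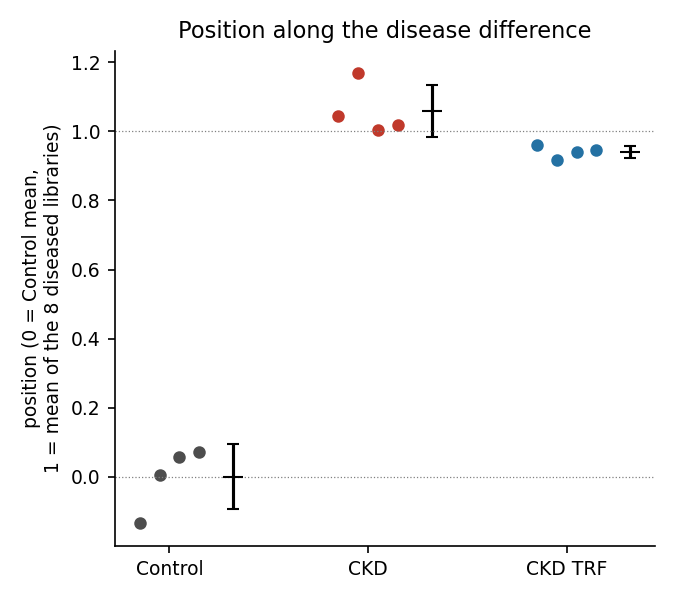
Vertical axis: position of each library along the disease difference, without unit, 0 for the Control mean and 1 for the mean of the 8 diseased libraries; horizontal axis: group, with bars for the mean and SD of 4 libraries. The highest CKD TRF library lies at 0.96 and the lowest CKD library at 1.004.

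Circadian clock genes were followed because feeding hours can set the clock of peripheral organs. In CKD the repressor gene Per1 rose by 1.39 ± 0.36 (SE), Nfil3 by 1.28, Tsc22d3 by 0.90, Cry1 by 0.88, Arntl (Bmal1) by 0.55, Wee1 by 0.52 and Tspan4 by 0.38. The call of Tspan4 was lost in 13 of 27 settings, over which its adjusted p ran from 0.000597 to 0.149. The clock output genes Dbp (-1.48 ± 0.39), Tef (-1.03), Nr1d1 (-0.68), Hlf (-0.53) and Nr1d2 (-0.51) fell in CKD. Limma gave these 12 genes adjusted p between 5.52e-06 for Tef and 0.0341 for Tspan4. Calls were also lost for Wee1 in 3 settings, for Arntl, Nfil3, Per1 and Nr1d2 in 2 each and for Dbp in 1, mostly when libraries with high Adipoq were left out; Nr1d2 was lost with plain totals as well. Npas2, Per2, Per3, Cry2, Rora, Clock, Bhlhe40, Bhlhe41 and Usp2 were among the clock genes that did not pass in CKD, with values from -0.31 for Bhlhe41 to 0.34 for Per2. In CKD TRF against Control Cry1 (0.99), Nfil3 (0.98), Tsc22d3 (0.72) and Arntl (0.62) rose, and Dbp (-1.37), Tef (-1.11), Usp2 (-0.70), Nr1d2 (-0.66), Hlf (-0.63) and Nr1d1 (-0.56) fell. The call of Nfil3 was lost in 11 of 26 settings, with adjusted p from 0.00181 to 0.25. Tsc22d3, Arntl, Dbp, Hlf and Nr1d1 lost their calls when libraries with Adipoq over 3 were left out, and Nr1d1 also with plain totals; the lowest value of Tsc22d3 was 0.175 (adjusted p from 0.000264 to 0.654 over 27 settings). Between CKD TRF and CKD no clock gene passed over all genes, with Per1 at -0.82 ± 0.36 and Usp2 at -0.49 ± 0.14, and Usp2 passed when adjusted over the list alone. The list of positive limb genes had 3 of 7 members higher in CKD and 4 not passed (3 adjusted over the list alone), and the list of output genes 4 higher, 5 lower and 6 not passed of 15, the same adjusted over the list alone. Camera called neither clock list in CKD against Control, with adjusted p = 0.249 and adjusted p = 0.56. Fry and the exact permutation called the positive limb list higher (adjusted p = 0.0322 and adjusted p = 0.0424, with a range of 0.0322 to 0.572 over 29 settings). In CKD TRF against CKD camera called the output list lower at an adjusted p of 0.0462, and adjusted p = 0.568 with an estimated correlation. That call was lost in 18 of 30 settings, the replicate block, array weights and the 2 groups alone among them, with adjusted p from 0.00076 to 0.568. Ciart was under the filter, and the hour of collection was not known.

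**Figure D5:**
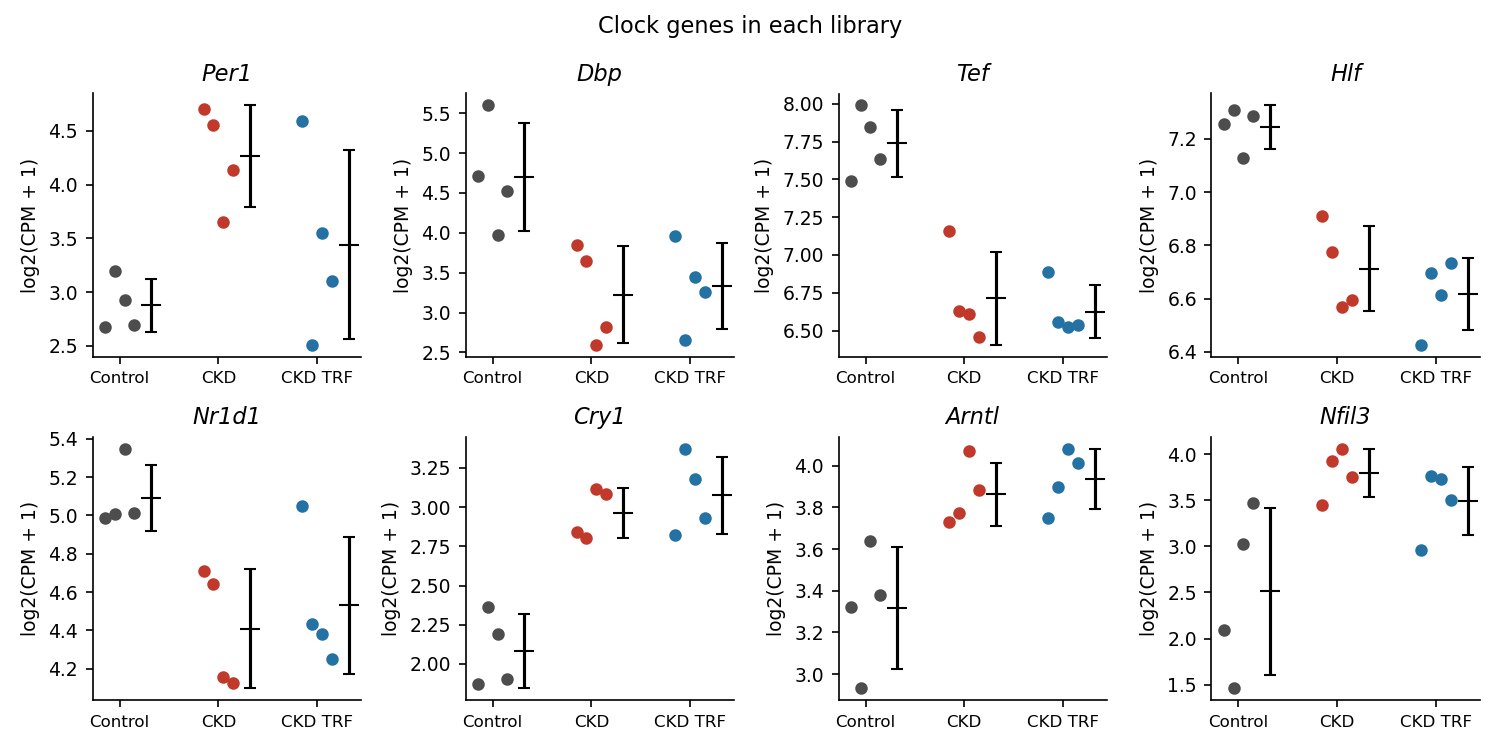
Each panel plots log2(CPM + 1) of a clock gene (vertical axis) in every library by group (horizontal axis), with bars for the mean and SD of 4 libraries; the vertical axes differ and do not start at 0. Tef averaged 7.74 in Control, 6.71 in CKD and 6.63 in CKD TRF.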

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

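Tests chosen only after the result was seen were the grouping of libraries by an Adipoq value over 3, plain totals, thinned reads and the permutation of list means, the labelings and the leaving out of CKD replicate 2 for the position of CKD TRF, the splitting of CKD libraries between both effects and the ratio test of adipocyte transcripts.

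A library far from the other 3 of its group was found by Dixon's test in 26 of 459 groups (5.7%), where chance gives 23, about 1 in 20. Among values on the log2 scale, these were Cfd in CKD TRF replicate 2 (0.339), Igfbp2 in CKD replicate 2 (5.277) and CKD TRF replicate 2 (3.285), Cckar in CKD TRF replicate 4 (6.964), Per2 in Control replicate 1 (1.948), Cry2 in Control replicate 2 (3.299), Nr1d1 in Control replicate 3 (5.347), Tef in CKD TRF replicate 1 (6.889) and Wee1 in CKD replicate 1 (4.185). Further genes were Col3a1 in CKD TRF replicate 3 (7.022), Il7r in Control replicate 2 (0), Sdhb in CKD TRF replicate 1 (9.514), Gata3 in CKD TRF replicate 2 (4.74), Ccdc151 in CKD TRF replicate 1 (3.294), Cdkn1a in Control replicate 2 (4.307) and Uqcrc2 in CKD TRF replicate 3 (9.085). Means of gene lists were principal cell in CKD TRF replicate 2 (4.957), podocyte in CKD replicate 4 (5.126), fatty acid oxidation in Control replicate 1 (7.118), cholesterol synthesis in Control replicate 2 (5.088), NRF2 and glutathione in Control replicate 1 (7.007), cell cycle in Control replicate 2 (2.91), autophagy and lysosome in CKD TRF replicate 3 (6.504), vitamin D, phosphate and calcium handling in Control replicate 2 (6.548) and immediate early genes in CKD TRF replicate 2 (4.769). The Kap share of reads in CKD replicate 2 was 2.34%. Control replicate 2 held 6 of the 26 values and CKD TRF replicate 2 held 5.

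The difference between CKD and Control was set against other splits of the 8 libraries, carried fat and depth. Of 35 splits 1, the real one, called as many genes (5878, highest other 0). No smaller share can come from 35 splits, and every other split mixes the groups, so the splits alone do not exclude chance. For lists 5 of 35 called as many (24, highest other 27), the others each with 3 Control libraries on 1 side and so with much of the real difference. The number of lists therefore does not decide. The exact permutation of list means called 29 lists (adjusted p = 0.0424), all at its smallest p of 0.0286. Those calls rest on the same real split and do not exclude chance either. In the CKD libraries with little Adipoq the called genes kept a median of 0.988 of their difference. Calls favor genes that vary little among all CKD libraries, and the libraries with little Adipoq enter both sides of this ratio. The ratio was thus held near 1 and does not decide. Leaving out CKD replicates 2 and 4, chosen after seeing the data, 4308 genes were called, 4235 of them shared. For these 4235 genes this argues against the fat of those 2 libraries as the cause. With reads thinned to the shallowest library the median ratio was 1. Thinning keeps the expected CPM of each gene, so this ratio could hardly move and does not decide on depth. The authors' scaling stays open for the share of higher genes, since plain totals gave 4474 higher and 1511 lower, and the disease may be the cause of the gene calls, as a hypothesis.

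The second pattern is that CKD TRF libraries lay between Control and CKD on the position measure. Not every list did so. In Control, CKD and CKD TRF the means were 3.82, 5.77 and 5.46 for the matrix list and 8.82, 8.08 and 8.21 for the proximal tubule. They were 6.86, 6.72 and 6.6 for fatty acid oxidation and 5.3, 5.26 and 5.45 for cholesterol synthesis, where CKD TRF did not lie between. Between CKD TRF and CKD the real split called 0 genes, so that 35 of 35 splits reach it whatever the data (highest other 6) and decide nothing, and 2 of 35 called as many lists (18, highest other 18), which does not exclude chance. Against Control 1 of 35 splits called as many genes (4930, highest other 0). That is again the smallest share that 35 splits can give and does not exclude chance. As many lists were called in 4 of 35 (25, highest other 27), the others each with 3 Control libraries on 1 side. The exact permutation of list means called 26 lists (adjusted p = 0.0473), all at its smallest p of 0.0286, which does not exclude chance either. For the position, 2 of 70 labelings gave a shift as large (-0.118, highest other 0.096 in size). This restates the separation already seen on the first principal component (22.7 to 35.2 in CKD, 15.9 to 19.8 in CKD TRF), so chance stays open. The covariance with no shared CKD libraries was -0.05 (SD 0.0151), which argues against shared libraries as the whole cause. With CKD replicate 2 left out of the average the shift was 0.694 of its size. That library still entered the choice of genes, weights and scale, so its part in the shift is not settled. Separate animals are not stated, so that feeding may have shifted the values only as a hypothesis.

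The third pattern is adipocyte transcripts, with Adipoq singled out after its values were seen: 58.7 and 38.1 CPM in CKD replicates 4 and 2 and 20.2, 16.1 and 9.84 CPM in CKD TRF replicates 4, 1 and 3. Of 15 listed genes 12 were measured, 6 of these are also expressed in Control kidney, and 1, Cfd, is in another list. Fat carried along with the kidney would keep 1 ratio to Adipoq; the SD of the log2 ratio over the SD of Adipoq had a median of 0.492 over 5 members and 5 libraries (SD 0.23, 0.222 to 0.819), where 0.5 was the bound, set after an earlier correlation measure was replaced. Fat carried along and fat cells within the kidney cannot be told apart, because either would keep 1 ratio to Adipoq at any value of this measure and no library was made from fat alone. No biological explanation was tested.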

How the results depend on the processing

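Settings chosen only after seeing the data were limma-voom, plain totals, thinned reads, the adipocyte covariate, both ways of leaving out libraries with Adipoq and the permutation of list means. For genes picked for the text, fold changes kept their side of the threshold in 1991 of 2039 gene values for CKD against Control (43 weaker, 5 stronger, 0 reversed). They did so in all 1145 for CKD TRF against CKD, where these settings called no gene. For CKD TRF against Control it was 1381 of 1418 (31 weaker, 6 stronger, 0 reversed). Here reversed means that the direction turned for a result called as reported or in that setting. Many of these genes were picked for their changes in the same data, so few losses were likely from the start. Of all 5878 genes called between CKD and Control, 4394 were also called with plain totals and 4528 with quantile normalization. Fold changes of 6, 12 and 7 named genes, none of them called as reported, changed sign in at least 1 setting. List values kept their side of the threshold in 1194, 1118 and 1209 of 1287 (47, 144 and 54 weaker, 45, 22 and 23 stronger, 1, 3 and 1 reversed). With at least 2-fold change 983 genes were higher and 295 lower in CKD than Control and 797 and 166 in CKD TRF than Control; at an unadjusted p these were 992 and 296, 806 and 170, and 4 and 4 for CKD TRF against CKD. Camera with an estimated correlation called 8, 0 and 7 lists (CKD against Control, CKD TRF against CKD, CKD TRF against Control). Fry and the permutation called 0 between CKD TRF and CKD, the permutation being limited by its smallest p of 0.0286. In that comparison 10 lists were called with quantile normalization and 12 with thinned reads. The stricter filter, which tests fewer genes, gave 1777 higher genes in CKD and 1523 in CKD TRF. Plain totals gave 4474 higher and 1511 lower in CKD and 1402 lower in CKD TRF, since every gene of a library moves by its factor. Leaving out libraries with Adipoq over 3 gave 1861 higher and 1946 lower in CKD and 769 and 704 in CKD TRF, with a correlation of disease and feeding effect of -0.349; fewer libraries were fitted, and the lone CKD TRF library is assumed to vary like the other groups.

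Leave-one-out ranges were 2466 to 2875 higher and 2580 to 2973 lower genes and 21 to 27 lists in CKD against Control; 0 to 0 genes and 10 (without CKD replicate 2) to 18 lists in CKD TRF against CKD; and 2110 to 2459 higher, 2065 to 2446 lower and 24 to 27 lists in CKD TRF against Control. The correlation ran from -0.552 to -0.416. The cross-fitted share was computed only without each CKD TRF replicate in turn (0.856 to 0.867), not without a CKD or Control library. The tested direction turned, with a call as reported or in that setting, for the lists of ribosomal proteins in CKD TRF against Control with quantile normalization (0.056), cell cycle in CKD against Control with the stricter filter (-0.048), MHC class II (0.256) and interferon response (0.203) in CKD TRF against CKD when libraries with Adipoq over 3 were left out, and adipocyte transcripts in CKD TRF against CKD without CKD replicates 2 and 4 (1.121); the cause was not tested. List means, called or not, changed sign in at least 1 setting for 10, 23 and 9 lists, of which those called as reported were fatty acid oxidation and cell cycle, the unfolded protein response and macrophages, and ribosomal proteins. A floor of 3 reads limits what depth can show, and totals differ between groups.

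With the replicate block, 2796 higher and 2892 lower genes and 25 lists were called in CKD against Control, 0 and 0 genes and 15 lists in CKD TRF against CKD, and 2381 and 2372 genes and 25 lists in CKD TRF against Control, with r = -0.506 for disease and feeding effect. No sign of pairing by number was seen: over 12 pairs with the same number r ran from -0.2 to 0.15, and 1 was over 0.1. Over the 36 other pairs r ran from -0.19 to 0.2. With 4 libraries per group a weak pairing would be missed, so it is not excluded.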

Other observations

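Tests in this part chosen only after the result was seen were the permutation of list means, plain totals, the voom fit, the adipocyte covariate and leaving out libraries by Adipoq. The other list tests were fixed before.

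Further lists were called by camera in CKD against Control. Endothelial markers had 9 of 23 members higher, 1 lower and 13 not passed (9 and 1 adjusted over the list alone), with a list adjusted p of 0.0474, and adjusted p = 0.395 with an estimated correlation. The call was lost in 9 of 30 settings, the adipocyte covariate and leaving out libraries with high Adipoq among them. The endothelial mean was 4.99 and 5.026 in CKD replicates 2 and 4, where Adipoq was high. It was 4.845 and 4.888 in CKD replicates 1 and 3, and at most 4.736 in Control. Glucocorticoid and fasting response had 10 of 21 higher, 2 lower and 9 not passed, the same adjusted over the list alone (adjusted p = 0.0173, and adjusted p = 0.393 with an estimated correlation). The glucocorticoid call was also lost with the adipocyte list as a covariate. Cell cycle had 12 of 25 higher, 1 lower and 12 not passed, the same adjusted over the list alone (adjusted p = 0.0292, and adjusted p = 0.281 with an estimated correlation), and its mean of 0.41 was -0.048 with the stricter filter. Immediate early genes had 7 of 17 higher and 10 not passed (7 adjusted over the list alone), with adjusted p = 0.0021, adjusted p = 0.457 with an estimated correlation and adjusted p = 0.14 by the exact permutation test. The mean of the immediate early genes was 5.37 in Control replicate 2, above 3 of the 4 CKD libraries, and at most 4.12 in the other Control libraries. The renin-angiotensin and kallikrein list had 5 of 11 lower and 6 not passed (5 adjusted over the list alone), with adjusted p = 0.0452, and adjusted p = 0.289 with an estimated correlation; this call was lost in 11 of 30 settings. In CKD TRF against Control thick ascending limb (adjusted p = 0.0474, and adjusted p = 0.518 with an estimated correlation, lost in 17 of 30 settings) and apoptosis (adjusted p = 0.02, and adjusted p = 0.231 with an estimated correlation) were called besides these, and glucocorticoid response was not (adjusted p = 0.0918). Camera did not call B and plasma cell markers in CKD against Control (adjusted p = 0.098). Only 5 of 20 were measured, of which 4 rose and 1 did not pass, the same adjusted over the list alone. That list was called higher by fry, by the exact permutation (adjusted p = 0.0424) and without a filter, with adjusted p from 0.000304 to 0.252 over 29 settings.

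Limma-voom on the recovered reads called 5727 genes between CKD and Control, of which 5712 are shared with the limma calls on log values, 0 between CKD TRF and CKD, and 4705 between CKD TRF and Control, of which 4697 are shared.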
